A study of Mus musculus with 6 samples.

How the data were processed

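RNA was measured by sequencing in 6 mouse heart samples, called hearts below, 3 from STAT3cKO mice, in which STAT3 was deleted in cardiomyocytes, and 3 from wild-type mice. The labels give genotype as the only factor. They state no age, sex, litter or batch, do not say whether each library came from a separate animal, and do not name the Cre line used for the deletion. Titles carry a number per sample (91, 6 and 3 for STAT3cKO, 1, 3 and 4 for wild type), and these numbers name the replicates here. If the libraries are not from separate animals, the p-values measure only the spread between these samples, which may be technical.

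Per the labels' protocols, total RNA was extracted with Trizol, RNA with an integrity number over 8 was taken for libraries, and libraries followed standard Illumina protocols. Per the submitters' processing notes, HISAT2 (version not given in the sources used here) and the mouse build GRCm38 were used. The deposited table holds raw read counts per gene, as whole numbers for each heart, with no normalization by the authors. The counting program, its annotation, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Genes that overlap, or that share near-identical copies such as the globin genes, are therefore uncertain. Beside those noted in the results, the following genes of the naming rule overlap another annotated gene, often a predicted model or a small RNA, and their counts are uncertain to an unknown extent: Ano5, Ccdc3, Rcan1, Myl2, Gja5, Cacna1h, Cpt1b, Acsl1, Pfkfb1, Pfkfb2, Cox6a2, Ndufa2, Prdx1, Ccl6, Flt1, Kdr, Bnip3, Dnajb11, Lamc1, Cdh5, Smtn, Notch3, Csf1r, Cx3cr1, Tnnt3, Casq1 and Ddx3y. Overlaps were not listed for genes named outside that rule.

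The table lists 46095 genes by symbol, of which 21080 had no count in any heart. Symbols were matched to an NCBI RefSeq gene table of GRCm38.p6 for coordinates (41483 symbols, 90.0%) and to GENCODE M21 transcripts of GRCm38 for transcript length and GC content (33980 symbols, 73.7%). Of the genes tested, 93.8% had a transcript length. Gene symbols of mitochondrially encoded transcripts are written as in the table (ND3, COX2), and these genes had no transcript length. Total counts per heart ran from 15416877 to 18264052. The smallest library was STAT3cKO replicate 3 and the deepest was wild type replicate 1.

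Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10, which left 14484 genes. Counts were scaled by TMM and compared with edgeR's robust quasi-likelihood F test, with genotype as the only term, in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes under 0.05 are described as higher, lower or changed. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. CPM values are TMM-normalised and given as mean ± SD over the 3 hearts of a group. All log2 fold changes are STAT3cKO minus wild type.

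Before the data were examined, 31 gene lists were fixed: pathways of the heart and of STAT3 signalling, markers of the other cell types and tissues a heart sample could hold, and lists for quality and confounders (mitochondrial transcripts, sex-linked, clock and immediate-early genes). Each was tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes and adjustment over the 31 lists. The estimated correlation for each list and fry were run beside it. No gene stands in more than 1 list. Also fixed before the data were examined was the rule for named genes. It took Stat3, then the 10 largest increases and the 10 largest decreases among genes that passed, had a mean of at least 1 log2 CPM and showed no overlap between the groups. Models known only by an identifier, pseudogenes and mitochondrial genes were left out. It also took up to 4 members of each list with the smallest adjusted p under 0.05, or the member with the smallest p where none passed, given by value only. Any gene named outside that rule is stated to have been chosen after its values were seen. Some genes that the rule takes are not reported here by name, and they remain in the counts.

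The alternatives planned in advance were DESeq2 size factors, upper-quartile factors and library size alone in the same edgeR fit. Others were no low-count filter, a stricter filter (at least 1 CPM in at least 3 libraries and a mean count of at least 50), DESeq2 1.42.0 (Wald test), limma-voom, edgeR without robust estimation, removal of mitochondrial and haemoglobin genes, a 2-fold minimum and leaving out each heart in turn. After the data were seen, a further fit was added in which a trend of log2 CPM on log2 transcript length and GC content (splines with 5 degrees of freedom, fitted to each heart) was entered as an offset. It is called the length and GC offset, and its trend was fitted to each gene's deviation from its mean over all hearts. Genes without a length received the median deviation of such genes.

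The edgeR fit was tested on simulated counts for the 14484 genes with the real means, library sizes and spread of the comparison of STAT3cKO with wild type, in 5 draws. It recovered 36.4% of genes changed by 1.5-fold, 73.6% of those changed by 2-fold and 90.3% of those changed by 4-fold, and 10.2% of its calls fell on unchanged genes. When a length trend between the groups was built into the same simulated comparison, 79.3% of the calls of the fit without an offset fell on unchanged genes, against 9.14% with the length and GC offset. In these simulations 14284 genes were unchanged, so such shares cannot be carried over to the real data. The built-in trend was linear in log2 length and equal in all hearts of a group, a form that the offset can fit by its design. In 1 further draw, a simulated list of 25 shifted genes was called by camera (adjusted p = 3.69e-10), and 0 of 25 unshifted lists were. Simulated genes were drawn independently, so this cannot show how the preset correlation performs on real lists whose genes vary together. Counts between hearts of one group gave a chi-square of 8.50 to 26.9 per degree of freedom, against 1 for sampling noise, so no library repeats another.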

Results

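Gene expression was measured by RNA sequencing in 3 heart samples from mice with a cardiomyocyte-specific deletion of STAT3 (STAT3cKO) and 3 from wild-type mice. STAT3 is a transcription factor activated by cytokines of the IL-6 family, and the series asked which pathways relevant to heart function differ when cardiomyocytes lack it. Wild type replicates 1, 3 and 4 held 18264052, 16168682 and 17921036 counts. STAT3cKO replicates 3, 6 and 91 held 15416877, 16911430 and 17867944. The first principal component of log2 CPM carried 54.6% of the variance and separated the groups, and the second carried 13.4%.

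Stat3, the deleted gene (GRCm38 chromosome 11, 100886806 to 100939594), was lower in every STAT3cKO heart than in every wild-type heart. Its level was 94.4 ± 7.46 CPM in wild type (SD, n = 3) and 58.7 ± 5.48 CPM in STAT3cKO (SD, n = 3), a log2 fold change of -0.68 ± 0.10 (SE; edgeR adjusted p = 0.000677). Heart RNA also holds the transcripts of cells in which the gene was not deleted, and gene-level counts include exons outside a deleted part. Its log2 fold change was -0.40 with the length and GC offset (edgeR adjusted p = 0.0116).

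The groups differed widely. Of 14484 genes tested, 1918 were higher and 1820 lower in STAT3cKO hearts (edgeR, 25.8% of the genes tested), and of these 342 were higher and 372 lower by at least 2-fold. At an unadjusted p under 0.05, 5586 genes passed. The groups did not overlap for 43.0% of the genes tested, against 10% by chance for 3 against 3. With library size as the only scaling, the median log2 fold change of all genes moved from 0.00 to -0.11 and the calls became 1109 higher and 2714 lower, so 29.0% of calls were higher in place of 51.3%.

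Fold changes also followed transcript length. Across the 13580 genes with a known length, Spearman's rho between length and log2 fold change was -0.463 (across genes, which are not independent replicates). Among the shortest 10% of genes (56 to 1090 nt) the median log2 fold change was 0.46, and 37.2% were higher and 1.18% lower. Among the longest 10% (6676 to 123179 nt) the median was -0.31, and 2.95% were higher and 40.01% lower. For each heart, the deviation of log2 CPM from the gene's mean over all hearts was regressed on length, so the slopes only compare hearts with each other. The slope per doubling of length was 0.053, 0.112 and 0.152 in wild type replicates 1, 3 and 4 and -0.114, -0.085 and -0.117 in STAT3cKO replicates 3, 6 and 91 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). With the length and GC offset, 1505 genes were higher and 1082 lower, and 1984 genes passed both fits in the same direction (1095 higher, 889 lower).

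**Figure D1:**
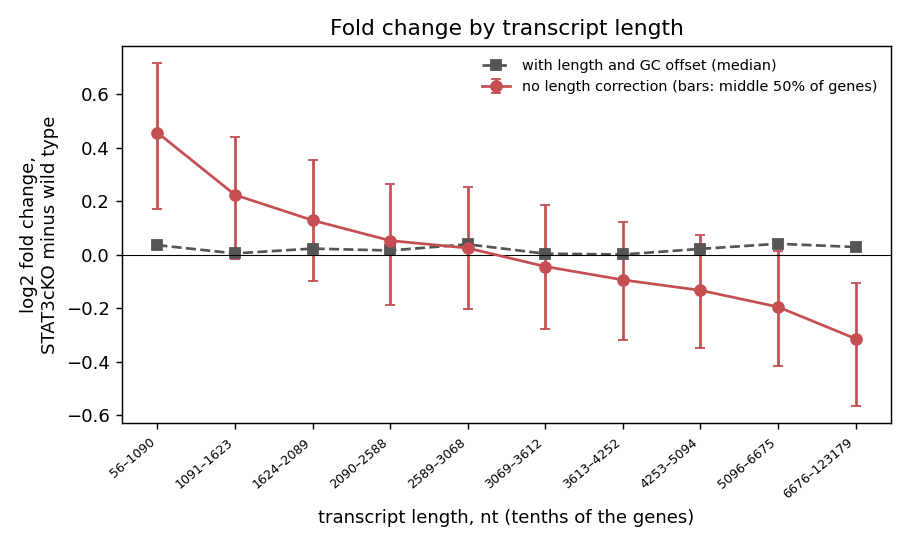
Median log2 fold change (STAT3cKO minus wild type, y axis) of genes in bins of 10% by transcript length in nt (x axis), without a length correction (circles, bars for the middle 50% of genes) and with the length and GC offset (squares). The median fell from 0.46 in the shortest bin to -0.31 in the longest without the correction.

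The largest increase was in reads assigned to Esr1, which encodes estrogen receptor alpha (chromosome 10, 4611989 to 5005633). Esr1 stood at 4.19 ± 3.26 CPM in wild type and 1931 ± 726 CPM in STAT3cKO (SD, n = 3 each), a log2 fold change of 8.83 ± 0.80 (SE; edgeR adjusted p = 0.00357). Raw counts were 149, 62 and 22 in the wild-type hearts and 40438, 25096 and 25668 in the STAT3cKO hearts. Gene-level counts do not show which part of Esr1 was read.

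Another 4 genes with large differences, higher in STAT3cKO than in wild type, were neighbours on chromosome 11. Mrps23, a protein of the mitochondrial ribosome, went from 3.33 ± 2.02 to 92.3 ± 4.39 CPM (log2 fold change 4.79 ± 0.35, edgeR adjusted p = 0.000677), and Cuedc1 from 1.69 ± 0.305 to 43.3 ± 2.005 CPM (4.68 ± 0.14, adjusted p = 2.02e-09). Srsf1, a splicing factor, went from 2.38 ± 0.555 to 34.3 ± 3.28 CPM (3.86 ± 0.17, adjusted p = 6.94e-08), and Vezf1, a zinc finger transcription factor, from 1.44 ± 0.174 to 17.9 ± 0.252 CPM (3.62 ± 0.16, adjusted p = 8.35e-08). Srsf1 starts at 88046499, Vezf1 at 88068199, Cuedc1 at 88099146 and Mrps23 at 88194106, where it overlaps the end of Cuedc1, so the counts of this pair are uncertain. A gene model beside them, Gm38534 (88230958 to 88259331), chosen after its values were seen, held 2, 0 and 0 counts in wild type and 111, 111 and 124 in STAT3cKO. The tested genes on either side, also chosen after their values were seen, were Dynll2 with a log2 fold change of -0.21 (edgeR adjusted p = 0.222) and Msi2 with -0.41 (adjusted p = 0.0202, and 0.318 with the length and GC offset).

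**Figure D2:**
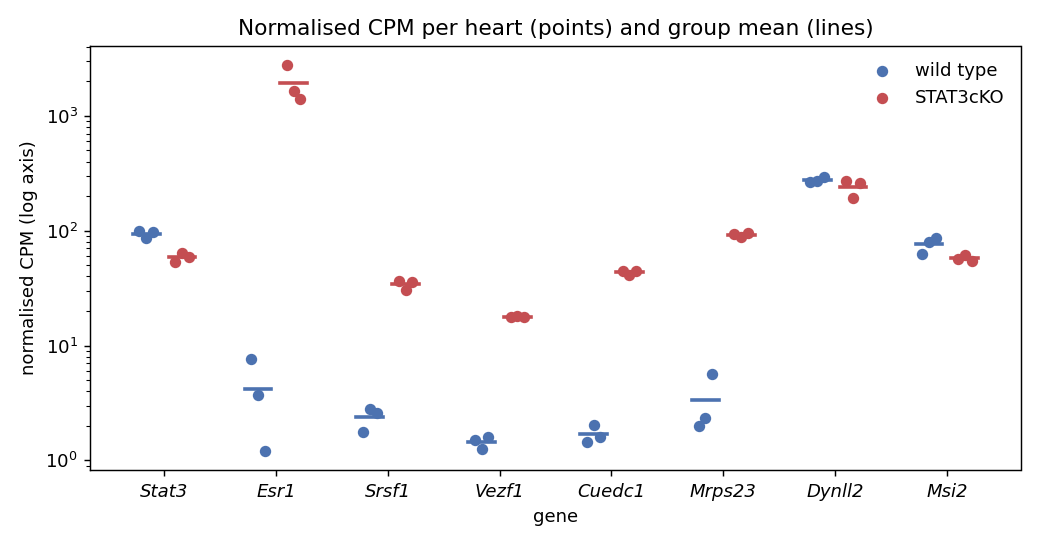
Normalised CPM (log y axis) of Stat3, Esr1, 4 neighbouring genes of chromosome 11 and their flanking genes Dynll2 and Msi2 (x axis) in each wild-type (blue) and STAT3cKO (red) heart, with a line at each group mean. Esr1 averaged 4.19 CPM in wild type and 1931 CPM in STAT3cKO, and Srsf1, Vezf1, Cuedc1 and Mrps23 did not overlap between the groups.

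**Figure D3:**
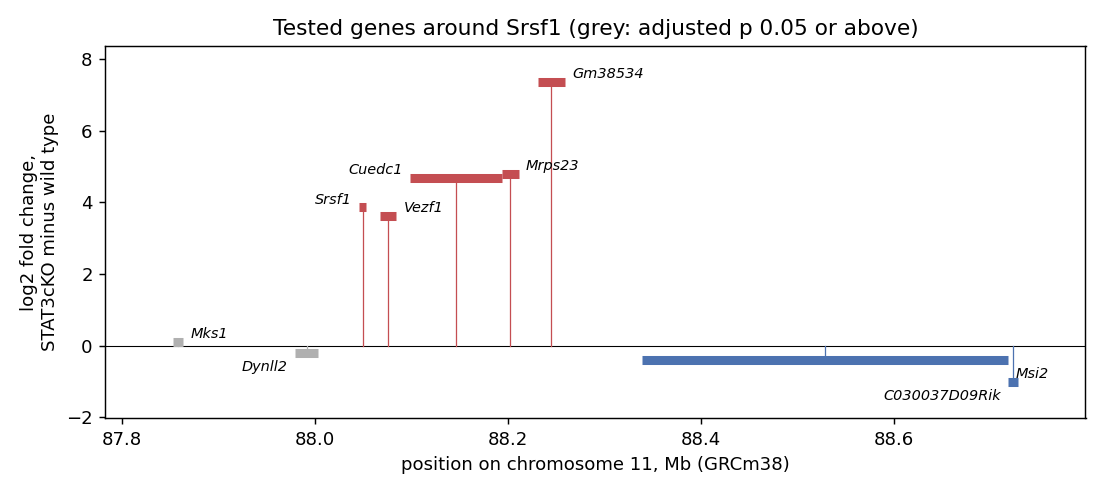
Map of tested genes on chromosome 11 around Srsf1 (x axis, Mb of GRCm38), each gene drawn from its start to its end at its log2 fold change, STAT3cKO minus wild type (y axis), in red or blue where the adjusted p was under 0.05 and grey otherwise. Genes from Srsf1 to Gm38534 had log2 fold changes from 3.62 to 7.35, and Dynll2 and Msi2 beside them had -0.21 and -0.41.

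The other large increases included Mir208a (log2 fold change 3.57), which lies inside Myh6 and whose reads cannot be separated from that gene here, Erdr1 (3.13), Gdf15 (3.06), a cytokine released by stressed cells, and Gng8 (2.52). Of the genes taken by the rule for largest changes, the largest decrease was that of Slfn8, a Schlafen family gene on chromosome 11, from 6.51 ± 1.24 to 0.220 ± 0.0985 CPM (log2 fold change -4.80 ± 0.35, edgeR adjusted p = 6.54e-06). Ano5 (-3.08), Sost (-2.63), an inhibitor of Wnt signalling, Zbed6 (-2.62), which overlaps Zc3h11a, Zfp369 (-2.46), and Retnla (-2.46), expressed by alternatively activated macrophages, followed. Among the same decreases were the smooth muscle genes Myh11 (-2.78) and Lmod1 (-2.58), and Ccdc3 (-2.33). The Myh11 call was lost without STAT3cKO replicate 91 (edgeR adjusted p = 0.0556). The Ccdc3 call was lost without wild type replicate 1 (adjusted p = 0.054), STAT3cKO replicate 3 (0.0635) or STAT3cKO replicate 91 (0.122). The remaining 18 of the 20 genes taken by that rule passed in each fit that left out 1 heart, and all 20 passed with the length and GC offset. Erdr1 had no transcript length, so the offset did not correct it for length.

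Genes for mitochondrial respiration were higher in STAT3cKO hearts. Of 45 nuclear-encoded genes of oxidative phosphorylation, 26 rose, 1 fell and 18 did not pass (26 and 2 adjusted over the list alone). Cox6a2, a heart and muscle subunit of cytochrome c oxidase, rose from 1133 ± 64.8 to 1930 ± 48.1 CPM (log2 fold change 0.77 ± 0.10, edgeR adjusted p = 0.000352), and Ndufa2 (1.03), Ndufb5 (0.67) and Atp5o (0.69) rose with it. The list was called by camera (adjusted p = 1.27e-05; adjusted p = 0.803 with an estimated correlation). Its transcripts are short, with a median of 1142 nt, and with the length and GC offset 11 members rose and 3 fell, and the camera call was lost (adjusted p = 0.399). Without wild type replicate 3 or STAT3cKO replicate 3, 17 members rose.

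Of 13 mitochondrially encoded transcripts, 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them ND3 (log2 fold change 0.82), COX2 (0.60), ATP6 (0.55) and COX3 (0.50), of which ATP6 and COX3 overlap. Camera called the list (adjusted p = 0.00766; adjusted p = 0.803 with an estimated correlation). The call was lost without STAT3cKO replicate 6 (adjusted p = 0.0572) and with the length and GC offset (adjusted p = 0.0805, with 4 rising), and 9 members rose without STAT3cKO replicate 91. These transcripts had no length, so the offset gave them only the median deviation of genes without a length. The call lost with the offset therefore says nothing about their length or GC content. Genes of the mitochondrial chromosome took 28.3 ± 1.95% of counts in wild type and 30.4 ± 2.42% in STAT3cKO (SD, n = 3 each), a difference within the spread between hearts (two-sided exact permutation p = 0.3, smallest possible 0.1). In wild type ND3, COX2, ATP6 and COX3 averaged 24.9, 383, 117 and 212 CPM, a small part of that share. The treatment of reads that map to several places is not given, so the rise of these genes is uncertain.

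Of 26 antioxidant genes 13 rose and 1 fell (the same counts adjusted over the list alone). Gpx4, which reduces lipid peroxides, rose from 218 ± 10.9 to 423 ± 30.8 CPM (log2 fold change 0.95 ± 0.10, edgeR adjusted p = 7.61e-05), and the metallothioneins Mt1 (0.90) and Mt2 (0.97) and the peroxiredoxin Prdx1 (0.57) rose too. The list was called by camera (adjusted p = 0.014; adjusted p = 0.741 with an estimated correlation), but not without STAT3cKO replicate 6 (adjusted p = 0.056) nor with the length and GC offset (adjusted p = 0.0805), where 6 members rose and 1 fell. Without STAT3cKO replicate 6, 3 members fell.

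Genes of cardiac stress and the fetal programme were higher as a list, with 5 of 18 rising and 1 falling (5 and 1 adjusted over the list alone). Gdf15 rose from 1.01 ± 0.173 to 8.46 ± 5.44 CPM (log2 fold change 3.06 ± 0.51, edgeR adjusted p = 0.00464), and Csrp3 (0.48), a muscle LIM protein, and Enah (0.48), a regulator of actin, rose, as did Rcan1 (1.18), a target of calcineurin signalling. The Enah call was lost without wild type replicate 1 (edgeR adjusted p = 0.0599), and the Rcan1 call without wild type replicate 1, 3 or 4 (adjusted p = 0.0707, 0.0657 and 0.0869), and both with library size alone (adjusted p = 0.078 and 0.0661). Csrp3 did not pass with the length and GC offset (adjusted p = 0.291). Myh7, the fetal myosin heavy chain, chosen after its values were seen, was at 87.2, 103 and 108 CPM in wild type replicates 1, 3 and 4 and 364, 581 and 3424 CPM in STAT3cKO replicates 3, 6 and 91, and did not pass (edgeR adjusted p = 0.0754). Camera called these genes as a list (adjusted p = 0.0266; adjusted p = 0.803 with an estimated correlation). The call was lost without wild type replicate 1 (adjusted p = 0.0796), wild type replicate 3 (0.0531) or STAT3cKO replicate 91 (0.0567), and the number that rose was 3 without any 1 of the wild-type hearts. No member fell without wild type replicate 4 or STAT3cKO replicate 6 or 91. The length and GC offset left 3 higher and 0 lower (camera adjusted p = 0.0205).

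Genes of the adult sarcomere and calcium handling went both ways, with 6 of 25 rising and 2 falling (6 and 2 adjusted over the list alone; camera adjusted p = 0.351). Those that rose included the regulatory light chain Myl2, from 7317 ± 91.8 to 12720 ± 217 CPM (log2 fold change 0.80 ± 0.10, edgeR adjusted p = 0.000352), and the troponins Tnnc1 (0.82), Tnni3 (0.62) and Tnnt2 (0.55). Tnni3 and Tnnt2 did not pass with the length and GC offset (adjusted p = 0.105 and 0.0653), while the list did (7 rose, 1 fell, camera adjusted p = 0.0197; adjusted p = 0.903 with an estimated correlation and no offset). Only 4 members rose without wild type replicate 1 or 3 or STAT3cKO replicate 3.

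Cardiac ion channels and gap junction genes were lower. Of 23 measured, 12 fell and 0 rose (13 and 0 adjusted over the list alone). Gja5, a connexin of the conduction system and of arterial endothelium, fell from 11.3 ± 2.46 to 4.54 ± 0.381 CPM (log2 fold change -1.31 ± 0.19, edgeR adjusted p = 0.00067). The pacemaker channel Hcn4 (-1.39), the potassium channel Kcnj3 (-0.74) and the T-type calcium channel Cacna1h (-0.88) fell with it. As a list they were called by camera (adjusted p = 0.000412; adjusted p = 0.741 with an estimated correlation). The transcripts are long, with a median of 4221 nt, and with the length and GC offset 7 fell and 1 rose (camera adjusted p = 0.00438).

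Angiogenic factors and receptors were also lower, with 14 of 24 falling and 1 rising (16 and 2 adjusted over the list alone). The gene that rose was Vegfa, the main endothelial growth factor, from 264 ± 20.4 to 459 ± 41.7 CPM (log2 fold change 0.80 ± 0.10, edgeR adjusted p = 0.000379). Its receptors Flt1 (-0.82) and Kdr (-0.77) fell, and so did Apln (-1.43), which encodes the peptide apelin. Camera called the list (adjusted p = 0.000152; adjusted p = 0.249 with an estimated correlation), and with the length and GC offset 10 fell and 2 rose (camera adjusted p = 0.000161), and 2 also rose without STAT3cKO replicate 3. Endothelial markers fell beside them. Of 19, 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them Cdh5, from 274 ± 30.3 to 128 ± 10.5 CPM (log2 fold change -1.09 ± 0.11, edgeR adjusted p = 6.03e-05), Pecam1 (-0.69), Cav1 (-0.45) and Erg (-0.90). Erg did not pass without wild type replicate 3 (edgeR adjusted p = 0.0551). Camera called the endothelial list (adjusted p = 0.032; adjusted p = 0.803 with an estimated correlation), but not without wild type replicate 1 (adjusted p = 0.18) or STAT3cKO replicate 91 (0.0939). Without wild type replicate 1, 4 members fell and 2 rose, without wild type replicate 3, 4 fell, without STAT3cKO replicate 6, 1 rose, and with the length and GC offset 8 fell (camera adjusted p = 0.0011).

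Markers of smooth muscle and pericytes fell in 10 of 18 cases and 1 rose (12 and 1 adjusted over the list alone). Acta2, smooth muscle actin, fell from 124 ± 21.05 to 29.2 ± 2.67 CPM (log2 fold change -2.09 ± 0.13, edgeR adjusted p = 2.36e-06), and Notch3 (-0.76) and Cspg4 (-0.61) fell, while Smtn (0.87) rose. Cspg4 did not pass with the length and GC offset (adjusted p = 0.0535). The list was called by camera (adjusted p = 0.000384; adjusted p = 0.741 with an estimated correlation), also with the length and GC offset (7 fell, 1 rose, adjusted p = 0.00015).

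Macrophage and monocyte markers fell in 11 of 24 cases and 0 rose (the same counts adjusted over the list alone). Cd163, a scavenger receptor of resident macrophages, fell from 36.3 ± 3.46 to 11.3 ± 2.59 CPM (log2 fold change -1.68 ± 0.16, edgeR adjusted p = 6.03e-05), and Csf1r (-1.09), Itgam (-0.99) and Cx3cr1 (-1.25) fell too. Camera called these genes as a list (adjusted p = 0.00369; adjusted p = 0.803 with an estimated correlation). Without wild type replicate 1, 5 members fell, and without STAT3cKO replicate 3, 6 fell, while 1 rose without STAT3cKO replicate 6. With the length and GC offset 11 fell (camera adjusted p = 8.69e-05).

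**Figure D4:**
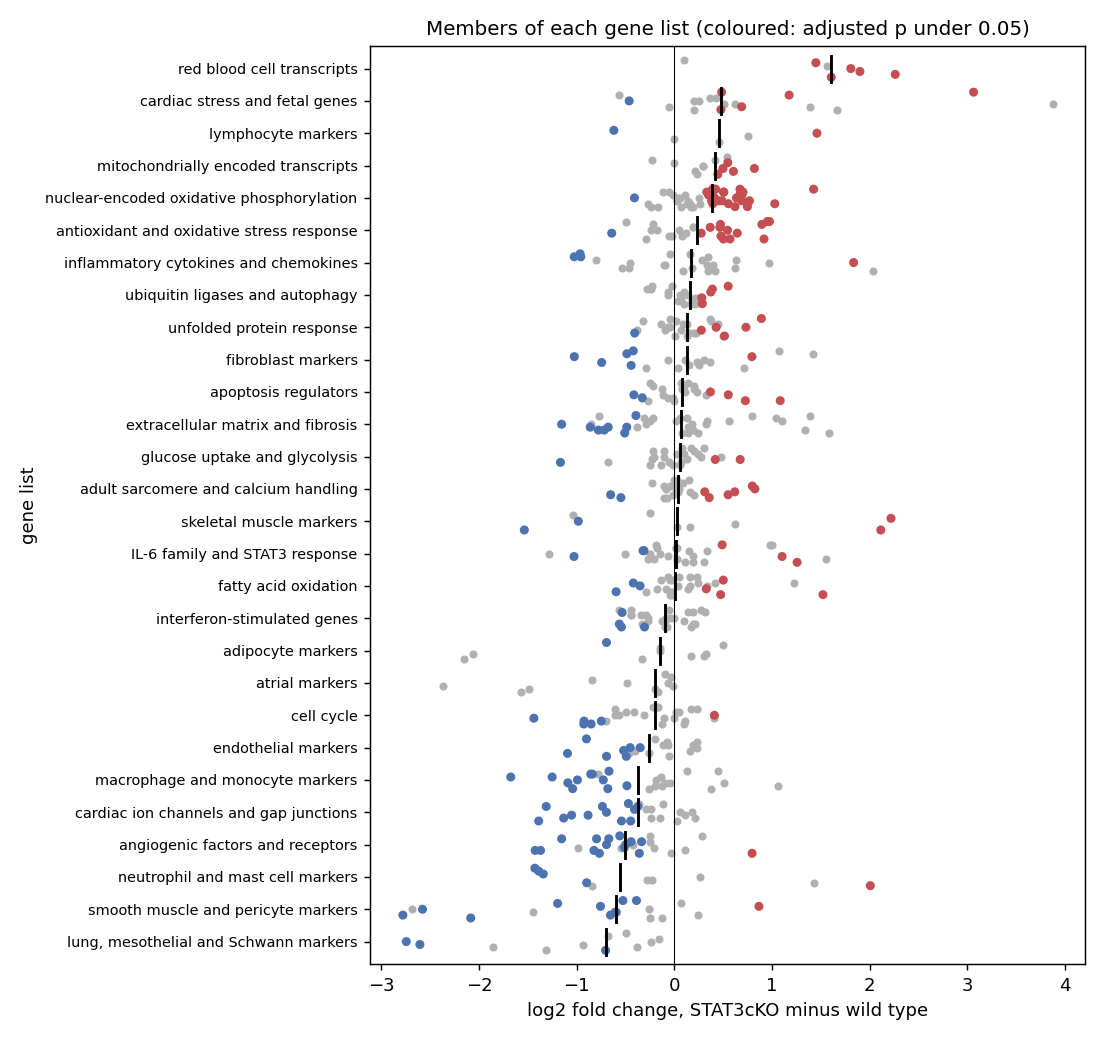
Log2 fold change (STAT3cKO minus wild type, x axis) of every measured member of the pathway, quality and cell type lists (y axis), in red or blue where the adjusted p was under 0.05 and grey otherwise, with a black line at each list's median. Medians ran from -0.70 for lung, mesothelial and Schwann markers to 1.61 for red blood cell transcripts.

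Markers of lung, mesothelium and Schwann cells fell in 3 of 11 cases and 0 rose (the same counts adjusted over the list alone). They were the Schwann cell genes Sox10 (log2 fold change -2.61) and Gfra3 (-2.75) and the mesothelial gene Upk3b (-0.70), which did not pass without wild type replicate 1 (edgeR adjusted p = 0.0724) or STAT3cKO replicate 3 (0.0556). As a list they were called by camera (adjusted p = 0.00498; adjusted p = 0.741 with an estimated correlation). Leaving out 1 heart gave 2 to 5 members that fell, 2 without wild type replicate 1 or STAT3cKO replicate 3 and 5 without STAT3cKO replicate 6.

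Red blood cell transcripts rose in 5 of 7 cases and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00309; adjusted p = 0.803 with an estimated correlation). Hbb-bs went from 67.6 ± 20.6 to 252 ± 104 CPM (log2 fold change 1.90 ± 0.41, edgeR adjusted p = 0.0305), and Hba-a2 (2.26) and Hbb-bt (1.81) rose. The globin genes have near-identical copies, so their counts are uncertain. None of the 5 passed without wild type replicate 1 or 4 or with the length and GC offset, 1 passed without wild type replicate 3 and 2 passed without STAT3cKO replicate 91. With the offset the list's median log2 fold change was 1.41, against 1.61 without it, and camera called the list (adjusted p = 0.00657). With no low-count filter Hba-a2, Hbb-bs and Hbb-bt did not pass (edgeR adjusted p = 0.0573, 0.0657 and 0.0851). Haemoglobin genes took 0.0128 ± 0.00367% of counts in wild type and 0.0419 ± 0.0161% in STAT3cKO (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible).

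Cell cycle genes fell in 5 of 26 cases and 1 rose (the same counts adjusted over the list alone). Cenpe (log2 fold change -1.44), Mki67 (-0.85) and Top2a (-0.75) fell and Pcna (0.41) rose. Mki67 and Top2a did not pass without wild type replicate 1 (edgeR adjusted p = 0.0566 and 0.0822), Top2a also not without wild type replicate 3 (0.0561) or STAT3cKO replicate 3 (0.0672), and Pcna not without wild type replicate 4 (0.0506) or with library size alone (0.0775). Mki67, Top2a and Pcna did not pass with the length and GC offset (adjusted p = 0.235, 0.0802 and 0.115). Camera called the list (adjusted p = 0.0266; adjusted p = 0.803 with an estimated correlation), but not without wild type replicate 1 (adjusted p = 0.0796) or STAT3cKO replicate 6 (0.0813). The number that fell was 1 without wild type replicate 1, 2 without wild type replicate 3 or STAT3cKO replicate 3, and 3 without wild type replicate 4, where 0 rose. The offset left 2 lower and 0 higher (camera adjusted p = 0.0263).

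Immediate-early genes, which respond within minutes to handling and other stimuli, rose in 7 of 20 cases and 0 fell (9 and 1 adjusted over the list alone). Maff rose from 5.20 ± 0.468 to 11.3 ± 3.31 CPM (log2 fold change 1.12 ± 0.21, edgeR adjusted p = 0.00291), and Fosb (2.89) rose, though not without wild type replicate 1 (edgeR adjusted p = 0.0535). The list was called by camera (adjusted p = 0.0174; adjusted p = 0.803 with an estimated correlation), but not without STAT3cKO replicate 6 (adjusted p = 0.0537). The number that rose was 3 without wild type replicate 1 or STAT3cKO replicate 91, 4 without wild type replicate 3 and 2 without wild type replicate 4, and 3 with the length and GC offset (camera adjusted p = 0.0139), and 1 fell without wild type replicate 3 or STAT3cKO replicate 6.

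The list of IL-6 family and STAT3 response genes was not called (camera adjusted p = 0.794). Of 28 measured, 3 rose and 3 fell (2 and 3 adjusted over the list alone). Il6ra, the IL-6 receptor, fell from 6.06 ± 0.815 to 2.94 ± 0.824 CPM (log2 fold change -1.03 ± 0.24, edgeR adjusted p = 0.00812), but did not pass with the length and GC offset (adjusted p = 0.0756), which left 1 gene of the list higher and 0 lower. Junb rose (1.10), but not without wild type replicate 3 or 4 or STAT3cKO replicate 91 (edgeR adjusted p = 0.0553, 0.07 and 0.0527) or with the length and GC offset (0.0803). Leaving out 1 heart gave 1 to 3 members that rose and 1 to 3 that fell, with the fewest on both sides without wild type replicate 1 or 3. Socs3, the classical STAT3 target, chosen after its values were seen, was at 4.40 ± 1.08 CPM in wild type and 5.0 ± 1.63 CPM in STAT3cKO (SD, n = 3 each; edgeR adjusted p = 0.633).

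Extracellular matrix genes fell in 8 of 34 cases and 0 rose (the same counts adjusted over the list alone), without a camera call (adjusted p = 0.442). The matrix protein Sparc fell from 465 ± 34.4 to 256 ± 25.5 CPM (log2 fold change -0.86 ± 0.10, edgeR adjusted p = 0.000271), and Fn1 (-1.16), Fbn1 (-0.68) and Col1a2 (-0.72) fell. Fbn1 did not pass with the length and GC offset (adjusted p = 0.226), which left 4 members lower. Camera called this list without STAT3cKO replicate 91 (adjusted p = 0.0272; adjusted p = 0.94 with an estimated correlation on all hearts), and 5 members fell without wild type replicate 3. Without that heart or without STAT3cKO replicate 3, 1 member rose. Fibroblast markers went both ways, with 5 of 18 falling and 1 rising (5 and 2 adjusted over the list alone; camera adjusted p = 0.993). Scara5 (-1.02) and Lamc1 (-0.75) fell, and Dcn, decorin, rose from 752 ± 185 to 1304 ± 167 CPM (0.79 ± 0.17, edgeR adjusted p = 0.00715). With the length and GC offset 2 rose and 2 fell, and 2 rose without wild type replicate 1 or 3 or STAT3cKO replicate 91.

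In fatty acid oxidation 4 of 28 genes rose and 3 fell (the same counts adjusted over the list alone; camera adjusted p = 0.719). Cpt1b, the muscle carnitine palmitoyltransferase, rose from 2.12 ± 0.242 to 6.13 ± 1.30 CPM (log2 fold change 1.52 ± 0.24, edgeR adjusted p = 0.000951), and Acsl1, an acyl-CoA synthetase, fell (-0.60). Cpt1b is among the genes listed above that overlap another gene, and its level was low beside Acsl1 (859 ± 74.7 CPM in wild type). Its rise is therefore uncertain. Under the length and GC offset 1 rose and 2 fell. Of 25 genes of glucose uptake and glycolysis, 2 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.731). These included Pfkfb2 (0.67) and Pfkfb1 (-1.17), isoforms of the enzyme that sets fructose 2,6-bisphosphate. Leaving out 1 heart changed the fatty acid counts to between 3 and 5 rising and between 1 and 5 falling, with 1 falling without wild type replicate 4 and 5 without STAT3cKO replicate 6, and 1 glycolytic gene rose without wild type replicate 1 or 3.

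Among inflammatory cytokines and chemokines 1 of 24 rose and 3 fell (the same counts adjusted over the list alone; camera adjusted p = 0.719). Ccl6 (log2 fold change -1.03), Cxcl12 (-0.97) and Nos2 (-0.96) fell and Cxcl1 rose (1.84), and 2 members rose without wild type replicate 1 or STAT3cKO replicate 6. Interferon-stimulated genes fell in 4 of 29 cases and 0 rose (3 and 0 adjusted over the list alone), among them Cmpk2 (-0.54). Camera did not call them (adjusted p = 0.0733), but did without wild type replicate 1 (adjusted p = 0.0397), without STAT3cKO replicate 91 (0.000115, with 8 falling) and with the length and GC offset (0.0139, with 3 falling). The list had a camera adjusted p = 0.903 with an estimated correlation on all hearts. Only 1 fell without wild type replicate 4 or STAT3cKO replicate 3.

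Apoptosis regulators rose in 4 of 24 cases and fell in 2 (the same counts adjusted over the list alone; camera adjusted p = 0.731), with Bnip3 (log2 fold change 0.55) higher and Xiap (-0.42) lower, the latter not with the length and GC offset (edgeR adjusted p = 0.205), which left 3 of the list higher and 0 lower. Unfolded protein response genes rose in 5 of 26 cases and 1, Dnajb11 (-0.41), fell (the same counts adjusted over the list alone; camera adjusted p = 0.222), and with the length and GC offset 3 rose and 1 fell. Of 24 ubiquitin ligases and autophagy genes 5 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0734), among them the autophagy receptor Sqstm1 (0.55). With the length and GC offset 8 of them rose and camera called the list (adjusted p = 0.0139; adjusted p = 0.741 with an estimated correlation and no offset). In these 3 lists only 1 to 3 members rose without wild type replicate 1, 3 or 4, without STAT3cKO replicate 3 or without STAT3cKO replicate 91. Without wild type replicate 4, 1 apoptosis regulator and 2 unfolded protein response genes fell, without wild type replicate 3 or STAT3cKO replicate 3 or 6, 1 apoptosis regulator fell, and without STAT3cKO replicate 6, 1 ubiquitin or autophagy gene fell.

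Of the remaining markers, neutrophil and mast cell genes fell in 4 of 10 cases and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.098), with Kit (log2 fold change -0.90) lower and S100a8 (2.01) higher. Camera called that list without wild type replicate 4 (adjusted p = 0.0414) and with the length and GC offset (adjusted p = 0.0205; adjusted p = 0.803 with an estimated correlation on all hearts and no offset), and 2 fell without wild type replicate 1 or 3 or STAT3cKO replicate 3 or 6. Without wild type replicate 1 or STAT3cKO replicate 3, 2 of its members also rose. Of 5 lymphocyte markers 1, Cd79b (1.46), rose and 1, Ptprc (-0.62), fell (the same counts adjusted over the list alone; camera adjusted p = 0.719). Cd79b did not pass without any 1 of the hearts other than STAT3cKO replicate 6 (edgeR adjusted p from 0.0709 to 0.218), with the length and GC offset (0.0854), with library size alone (0.0629), in DESeq2 (adjusted p = 0.0988) or in limma-voom (adjusted p = 0.0619). Of 10 adipocyte markers 1, Fasn (-0.70), fell and 0 rose (the same counts adjusted over the list alone; camera adjusted p = 0.695). Fasn did not pass without wild type replicate 3 (edgeR adjusted p = 0.054) or STAT3cKO replicate 6 (0.0619) or 91 (0.0778), and neither Fasn nor Ptprc passed with the length and GC offset (adjusted p = 0.222 and 0.0574). Other counts of adipocyte markers were 2 falling without wild type replicate 1, 1 rising without STAT3cKO replicate 6 and 2 rising without STAT3cKO replicate 91. Of 9 skeletal muscle markers 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.993), with Tnnt3 (2.11) higher and Casq1 (-1.54) lower. In that list 1 rose in each fit that left out a heart other than wild type replicate 3, and 1 fell without wild type replicate 1 or STAT3cKO replicate 91 and 3 without STAT3cKO replicate 3. Under the length and GC offset 1 skeletal muscle marker rose and 2 fell, and 1 adipocyte marker rose and 0 fell. Of 11 atrial markers 0 passed in edgeR, and the smallest p was that of Stard10 at 20.3 ± 6.35 and 14.5 ± 2.91 CPM (edgeR adjusted p = 0.146, and 0.00211 with no low-count filter; camera adjusted p = 0.371).

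Of 18 clock genes 1, Hlf (log2 fold change -0.54), fell and 0 rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.922), and it did not pass without any 1 of wild type replicates 1, 3 and 4 (edgeR adjusted p = 0.0807, 0.0867 and 0.139), without STAT3cKO replicate 3 (0.128) or 91 (0.135), or with the length and GC offset (0.201), under which 1 other clock gene rose. Without STAT3cKO replicate 6, 2 clock genes fell, and without STAT3cKO replicate 91, 1 rose. Of 5 sex-linked transcripts 0 passed (camera adjusted p = 0.677). Ddx3y, a gene of the Y chromosome, was at 92.5 ± 14.1 CPM in wild type and 77.0 ± 3.73 CPM in STAT3cKO (SD, n = 3 each; edgeR adjusted p = 0.0937, 0.0189 with library size alone, 0.0327 with no low-count filter and 0.0259 without wild type replicate 1). All 6 hearts held Y-linked transcripts. The direction of the camera test differed from the sign of both median and mean for the lists of IL-6 family and STAT3 response, extracellular matrix, inflammatory, fibroblast and skeletal muscle genes, none of which it called. None of the 13 camera calls held with an estimated correlation.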

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

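The length and GC offset and the count of genes that passed both fits were chosen after the data were seen, and the other alternatives were planned. The Stat3 log2 fold change kept its direction and passed under all 16 alternatives (-0.80 to -0.40, adjusted p from 7.6e-10 to 0.0116). The 3738 genes changed between STAT3cKO and wild-type hearts (1918 higher, 1820 lower) became 714 (342 higher, 372 lower) with a 2-fold minimum, by that limit's own construction. With library size alone 1109 were higher, because the median of all genes moved to -0.11. With the length and GC offset 1082 were lower, and 1984 passed both fits (1095 higher, 889 lower). Leaving out 1 heart gave 2435 to 3886 genes, 1237 to 1887 higher and 1198 to 1999 lower, with fewer samples in the fit. The fewest were without wild type replicate 4. Of the calls on all hearts, 63.0% to 85.7% were also made in those fits. The 13 gene lists called by camera became 0 with an estimated correlation and 5 with fry, of which ubiquitin ligases and autophagy was not among the 13, and 9 to 14 when 1 heart was left out. For the angiogenic list the estimated correlation was -0.003, below the preset of 0.01, yet its camera adjusted p went from 0.000152 to 0.249. The loss of that call therefore does not come from a higher correlation between its genes. The cause of the other losses was not tested. Of the 127 named genes besides Stat3, 88 kept their direction and side of the threshold in every fit without 1 heart, 33 calls were lost with the length and GC offset, and 0 reversed. Of all 3738 calls, 112 had the opposite sign with that offset. The sex-linked covariate was not run, because every heart held Y-linked transcripts. The labels give no sex, so the sex of the mice is not known beyond that. No paired analysis was possible because the groups share only 1 replicate number, 3. Of the 10 splits of the hearts into 3 and 3, only the real one, 1 split, called as many genes as 3738. The highest of the others was 0 in edgeR, with 147 to 441 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. Each of the others also mixed both genotypes within its groups. A difference between genotypes then widens the spread within groups, so few calls were likely from the start. At this depth the fit recovered 36.4% of simulated changes of 1.5-fold, so small changes can be missed.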

Other observations

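The tests of the fall of fold change with transcript length, of the large changes on chromosome 11 and of the Esr1 reads were chosen after those results were seen, and the genes of the next paragraph were chosen after their values were seen.

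Outside the lists, Nnt, the mitochondrial transhydrogenase (chromosome 13, 119335527 to 119409257), fell from 902 ± 25.6 to 393 ± 32.7 CPM (SD, n = 3 each; log2 fold change -1.20 ± 0.10, edgeR adjusted p = 2.32e-05, lower in 3 of 3 STAT3cKO hearts). On chromosome 19, Lipo2, a lipase gene (33719670 to 33762022), rose from 0.277 ± 0.146 to 3.49 ± 0.146 CPM (log2 fold change 3.63 ± 0.38, edgeR adjusted p = 9.91e-05). A1cf, an RNA-binding cofactor of apolipoprotein B editing (31868756 to 31952365 on the same chromosome), had 0 counts in each wild-type heart and 14, 7 and 9 in STAT3cKO replicates 3, 6 and 91. Against a floor of 3 counts over the wild-type group it was at least 10.4-fold higher, by counting error only, and it was below the count filter of the test. The test of a strain haplotype below asked only about chromosome 11. Whether a strain difference or any other genetic difference between the groups lies behind the values of Nnt, Lipo2 or A1cf was not tested.

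Log2 fold change fell by 0.212 per doubling of transcript length across all genes with a length (95% interval -0.221 to -0.204). The tables argue against a loss of cells other than cardiomyocytes as the whole reason: within 3 lists expressed by cardiomyocytes (sarcomere, fatty acid oxidation and oxidative phosphorylation) the slope was -0.169 (95% interval -0.235 to -0.104, 98 genes). Within all lists the slope was -0.214 (95% interval -0.267 to -0.161, 613 genes), as differences in RNA fragments or library preparation between the hearts would give. Such differences may have contributed. Some lists mix cell types, such as the lung, mesothelial and Schwann markers, so a change in cells could also act within a list. All hearts of each group lie on one side, so an effect of genotype on transcripts by length stays open and untested. Smooth muscle, macrophage and endothelial markers were still lower with the offset (7 of 18, 11 of 24 and 8 of 19 members). The median log2 fold change of smooth muscle markers went from -0.601 to -0.405, so the trend is not the whole reason for their fall. For macrophage markers it went from -0.371 to -0.5 and for endothelial markers from -0.263 to -0.326, a larger fall with the offset.

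Large changes on chromosome 11, where Stat3 lies, could come from a strain haplotype carried along with the targeted locus. Genes changed by at least 4-fold made up 12 of 1117 tested on chromosome 11 and 93 of 12597 elsewhere, with the 5 adjacent genes from Srsf1 to Gm38534 counted as 1 (odds ratio 1.46, one-sided Fisher exact p = 0.146). Within 5, 10 and 20 Mb of Stat3 there were 2, 3 and 7 such genes (one-sided Fisher exact p = 0.378, 0.325 and 0.0826), Slfn8 and Sost among the 7. None of these 4 tests passed, and so few genes leave the explanation open. Srsf1 and Mrps23 are widely expressed genes, so the unusual values of the adjacent genes may be the low ones in wild type (2.38 and 3.33 CPM), and it is open whether they differ through a structural variant in the wild-type or the STAT3cKO mice, through mapping or through loss of STAT3, since gene-level counts hold no sequence.

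Esr1 reads in STAT3cKO hearts could be reads of a Cre recombinase fused to the hormone-binding part of the estrogen receptor, a common tool for inducible deletion in cardiomyocytes. The lowest STAT3cKO heart stood 183-fold above the highest wild-type heart. Induction of the native gene could give the same value, and counts per exon, which could separate them, were not analysed here, so these explanations cannot be told apart. The labels do not name the Cre line. If the reads come from such a fusion, the groups also differ in carrying it. Its effects on other genes could then not be told apart from those of STAT3 loss.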
